A study of Mus musculus with 135 samples.

How the data were processed

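H3K4me3 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) of MNase-digested chromatin in 123 samples, and 12 further samples were input chromatin. The values of all comparisons come from the count tables deposited by the authors, whose unit is counts: whole-number reads per peak, not normalised, with a column for each H3K4me3 sample and 0 columns for the inputs. The deposited association lists give peak positions (unit: other, coordinates) on mm10 and on a second genome whose build is not given in the sources used here. Per the submitters' processing notes CASAVA 1.8, BWA 0.5.10, MACS 1.4.2 and genome build mm10 were used. The notes give no role or order for these tools, and which reads were counted, with which filters and on which strain genome, is not given in the sources used here. Peak names in the deposited tables mark peaks found on both genomes, on the reference genome alone or on the second genome alone.

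Columns were matched to samples by strain, cell type and replicate. The 3 germ cell columns of B6 are named B62, B63 and B64, numbers that the labels do not use, so they were taken as unnumbered replicates of B6, and replicate number could not be a block in comparisons with B6 germ cells. Germ cell libraries were made with the NEXTflex kit, those of the other cell types with the KAPA kit. Antibody lot 2557645 was used for the founders, F1 and part of the panel in germ cells, and lot 2746331 for the rest of the panel and for the other cell types. Stem cell libraries of 1 line (B6 line 49 and D2 line 203) were summed, so that the line was the replicate. Numbers pair replicates only if deviations from the group means go together. In hepatocytes 4 of 18 and in cardiomyocytes 8 of 18 pairs of libraries with the same number had a correlation over 0.1 across peaks, with ranges of -0.252 to 0.593 and -0.730 to 0.644, so number was not a block, and the blocked counts stand beside each result where they could be had.

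Peaks were placed against GENCODE M21 basic transcripts, and a peak within 1 kb of a transcription start site was called a promoter peak. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM normalisation, glmQLFit with robust estimation and the quasi-likelihood F test, with all strains of a cell type in 1 fit. Peaks with a Benjamini-Hochberg adjusted p under 0.05 were called. Contrasts were B6 minus D2, BXD75 minus BXD87, F1 minus each parent and F1 minus the mean of both parents on the log2 scale. The median log2 of all peaks lay within 0.1 of 0 in every comparison and scaling. Peaks called between the founders and between the lines were counted with their direction against the count that independence gives. The dependence of the founder difference on cell type was the F test of the strain by cell type terms over peaks matched at 50% reciprocal overlap with bedtools 2.31.1. Antibody lot was tested on strain totals, without BXD99, which has libraries of both lots.

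Gene lists were tested on promoter peaks, 1 peak per gene (a peak shared by members was counted for each member but entered camera once), with camera of limma 3.58.1 at a preset correlation of 0.01, repeated with an estimated correlation, and p values were adjusted over 59 tests. Of 13 lists called with the preset 1 was called with the estimated correlation, the cardiomyocyte list between BXD75 and BXD87. The lists were H3K4 methylation writers and erasers, KRAB silencing cofactors, zinc finger genes (all genes named Zfp), housekeeping, interferon response and histocompatibility genes in every cell type. Those of single cell types were meiotic prophase, spermatogonia, Sertoli and Leydig cells, hepatocyte, liver non-parenchymal cells, xenobiotic metabolism, cardiomyocyte, cardiac non-myocytes, naive pluripotency, lineage differentiation and 2-cell-like genes.

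In the BXD panel lot means were subtracted from log2 CPM and libraries averaged by strain. Genotypes were not used. The consensus of at least 3 marker peaks in each 5 Mb bin, signed so that B6 is up, stood in for the founder haplotype, and each peak was correlated with all bins, itself left out of the consensus. Marker peaks were founder-differential peaks whose best bin in a first pass over the same strains lay within 10 Mb of them. The permutations kept these markers. A peak was called when its best absolute r passed 0.462, the 95th percentile of the largest r of each peak over 100 permutations of the strains. It was local within 10 Mb and distal on another chromosome. The percentile was taken over all peaks and permutations together, so it does not limit false calls over the whole scan. By this definition a mean of 582 of 11631 peaks passed per permutation in each setting, so this number is not an observed result. Control peaks were peaks with a founder p over 0.5, matched in 20 bins of level. In the setting added after the data were seen, components were estimated from unchanged peaks that were not control peaks. Named r values have 100000 resamples. Strain variance was compared between founder-differential and unchanged peaks by permutation of the classes within level bins.

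The groups, tests, gene lists, most alternatives and the rule for named genes were chosen before the data were examined. The rule took called peaks with a mean CPM at or above the median of tested peaks and no overlap between the libraries of both groups. Among them it named the 6 largest log2 differences in each direction at promoters of named protein-coding genes and the 3 largest in each direction elsewhere. For each fitting list it took up to 4 members with the smallest adjusted p, called or not. It took 3 peaks in each direction for F1 against the mean of the parents, the 4 peaks with the smallest adjusted p for cell type, and for distal association 4 peaks at each of the 3 bins with most peaks. After the data were seen the rule was repeated among peaks with reads in both groups and under the added distal setting, and only part of the names it gives are printed. Where a group had no read, the fold was computed against a floor of 3 counts over the group. Such floors and intervals cover counting error only.

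Alternatives were DESeq2 1.42.0, RLE size factors, total counts, no filter, at least 50 reads in every library of a group, only the groups compared, each replicate left out, replicate number as a block, other bin sizes, ranks, single lots, 80% overlap and a linear scale for F1. Alternatives chosen after seeing the data were thinned cardiomyocyte libraries, summed pairs of like libraries and removed components. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 and the R package data.table (version 1.17.8) did the rest.

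The tests were tried on simulated data with 100 changed peaks at each fold. In single cell types the changes were placed only in peaks at or above the median level, so recovery at weaker peaks was not tried. At 2-fold, edgeR recovered 77% of them in a design like germ cells B6 and D2, 100% in hepatocytes, 90% in cardiomyocytes, 90% in stem cells and 91% for cell type, and at 4-fold 100% in each. The scan recovered 94.9% of 2800 simulated local effects and 97% of 200 distal ones. Of 1000 simulated unchanged peaks it called 1 local and 40 distal. The simulated strains had independent noise, with no variation shared by the panel, while the real scan called 43.2% of unchanged peaks distal. Replicates differed by more than counting: chi-square per degree of freedom between pairs was 3.25 to 13.0 in germ cells, 1.19 to 11.8 in hepatocytes, 1.54 to 17.5 in cardiomyocytes and 0.818 to 13.2 in stem cells. Pairs of libraries of 1 stem cell line stood at 0.818 to 0.986 for B6 line 49 and 0.858 for libraries 2 and 3 of D2 line 203, while its library 1 stood at 3.48 and 2.75 from these. Outside these lines the pairs nearest to 1 were BXD75 lines N and Y in stem cells (1.14) and BXD87 libraries 2 and 3 in hepatocytes (1.19). The depth of each group is given with the samples.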

Results

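The series set out to map loci that control H3K4me3, the trimethyl mark on lysine 4 of histone H3 that sits at active promoters and some enhancers and, in meiotic cells, at sites of recombination. The founders were C57BL/6J (B6) and DBA/2J (D2). Their descendants were BXD recombinant inbred lines, each a fixed mosaic of both founder genomes, and the F1 hybrid of B6 and D2. Male germ cells taken at 14 days post-partum came from 61 BXD lines (69 libraries), B6 (3 libraries), D2 (3) and F1 (4). Hepatocytes and cardiomyocytes came from females of 8 weeks, with 3 libraries each of B6, D2, BXD75 and BXD87. Embryonic stem cells, derived from embryos at day 3.5, had 5 libraries of each of these strains. These were 3 B6 and 3 D2 cell lines, some sequenced repeatedly, and 5 lines each of BXD75 and BXD87.

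Germ cells held 67114 peaks and stem cells 67192, of which 21.9% and 21.1% lay at a promoter. Hepatocytes held 29138 peaks, 37.9% at a promoter, and cardiomyocytes 23809, 48.9% at a promoter. Peaks found on the reference genome alone numbered 15724 in germ cells, 10216 in stem cells, 1814 in hepatocytes and 14804 in cardiomyocytes. Those found on the second genome alone numbered 3310, 8886, 3710 and 97. Reads in peaks ranged from 1.87 to 18.6 M (mega-reads) in BXD germ cell libraries, 6.93 to 16.4 M in B6, 8.73 to 30.3 M in D2 and 12.5 to 31.4 M in F1. Stem cell libraries held 13.8 to 20.2 M and hepatocyte libraries 8.95 to 25.2 M. Cardiomyocyte libraries of D2 were the shallowest, with 2.62 to 4.10 M against 6.84 to 8.34 M in B6, 7.15 to 7.65 M in BXD75 and 10.5 to 12.8 M in BXD87. Levels are CPM, scaled by normalised library size, as mean ± SD, and log2 differences are given with their standard error (SE) where marked. The p values of single peaks measure only the spread between these samples, because the labels do not say which libraries came from separate animals.

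Male germ cells of B6 and D2 were compared to find the peaks that differ between the founders. At the promoter of Frmd5, a FERM domain gene (chromosome 2, 121549556 to 121551980, in an intron), B6 stood at 30.7 ± 8.8 CPM and D2 at 1.13 ± 0.72 (n = 3 each), a log2 difference of 5.02 (SE 0.32) with an edgeR adjusted p of 7.9e-10. Fcho1, which works in clathrin-mediated endocytosis, was higher in B6 as well, at 39.0 ± 4.0 against 4.27 ± 1.0 CPM, and so was Apoa2, an apolipoprotein of high-density lipoprotein, at 15.1 ± 3.7 against 1.69 ± 0.48 CPM. Scnm1, a splicing factor whose peak is also at the promoter of Lysmd1, stood at 32.5 ± 4.8 against 7.17 ± 0.79 CPM. In the other direction, Syt11, a synaptotagmin of vesicle traffic (chromosome 3, 88770199 to 88773730, in an intron), stood at 1.57 ± 0.57 CPM in B6 and 53.2 ± 6.0 in D2, a log2 difference of -5.16 (SE 0.26). Mthfsl stood at 2.32 ± 0.42 against 68.4 ± 4.4 CPM, Mageb4, an X-linked gene of the MAGE family, at 0.384 ± 0.34 against 17.0 ± 0.93 CPM, and Nat8f7 at 0.0645 ± 0.065 against 14.8 ± 1.3 CPM.

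Away from promoters, a peak in an intron of Dlc1 (chromosome 8, 36568983 to 36572453) was higher in B6 by a log2 of 7.12 (SE 0.31), at 48.0 ± 13 against 0.369 ± 0.18 CPM. An intron peak of Ankfn1 differed by 9.21 and an intergenic peak nearest Klf5 by 7.70 on the log2 scale. Some promoters had no read in 1 founder. Cops7b, a subunit of the COP9 signalosome, stood at 37.2 ± 9.4 CPM in B6, at least 829-fold above D2, counting 3 reads over the 3 libraries as the floor. Zfp429, a zinc finger gene (chromosome 13, 67398623 to 67400595, in an intron), was at least 614-fold higher in B6 and Zfp960 at least 529-fold. Gm3448 stood at 473 ± 21 CPM in D2, at least 4988-fold above B6, and Duxbl3, a double homeobox gene, was at least 548-fold higher in D2. Germ cell peaks with no D2 read numbered 70, 20 of them at promoters, and those with no B6 read 55, 8 of them at promoters. In 99 of these 125 peaks at most 3 of the 61 BXD strains had a low level.

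In all, 11631 of 67101 tested germ cell peaks differed, 6192 higher in B6 and 5439 higher in D2, and 8453 of them by more than 2-fold. Of peaks at promoters 4.4% differed and of other peaks 21%, a contrast that was not tested because peaks are not independent. The named peaks had no overlap between the libraries of the founders, which chance gives in 10% of arrangements of 3 against 3. The count was 7639 (3819 higher in B6, 3820 lower) without the B6 library B64, and the majority was higher in D2 without B62 (4836 and 5286) or D2 library 2 (3639 and 4159). It was 5028 when every library of 1 group had to hold 50 reads. Of the 11631 calls 3920 were peaks found on the reference genome alone and 2522 on the second genome alone.

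Of 20 measured interferon response promoters 8 were higher in B6 germ cells, and 8 with p values adjusted over the list alone. Gbp2, an interferon-induced GTPase, stood at 21 ± 1.2 against 7.25 ± 1.2 CPM and Irf7, a transcription factor of the interferon response, at 17.4 ± 6.4 against 9.21 ± 0.26 CPM, although the Irf7 call was lost without the B6 library B64 (adjusted p = 0.0540). The list had an adjusted p of 5.4e-09 by camera, and an adjusted p of 0.386 with an estimated correlation. Meiotic prophase promoters, which belong to chromosome pairing and recombination, had a list median of -0.27 on the log2 scale over 37 members, with an adjusted p of 2.7e-05 and, with an estimated correlation, an adjusted p of 0.791. edgeR called 0 of these members at the adjusted threshold and 0 with p values adjusted over the list alone, 10 were lower and 0 higher at an unadjusted p under 0.05, and DESeq2 called 2 lower and 0 higher. Syce3 and Sycp3, of the synaptonemal complex, stood at 22.9 ± 2.0 against 30.6 ± 3.9 CPM and 74.2 ± 1.1 against 93.8 ± 2.7 CPM, and Spo11, which makes the meiotic double-strand breaks, at 17.7 ± 2.3 against 25 ± 1.1 CPM.

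Markers of somatic cells of the testis, which a crude germ cell preparation can hold, were read next. Of 14 Sertoli and Leydig members 2 were higher in B6 and 1 lower, with a list median log2 of 0.23 against -0.07 for all promoters (4 and 1 with p values adjusted over the list alone). Hsd3b1, a Leydig steroid enzyme, stood at 2.04 ± 0.30 against 7.40 ± 2.4 CPM, and Cldn11, a tight junction protein of Sertoli cells, at 55.8 ± 13 against 35.9 ± 5.0 CPM, a call lost without the B6 library B64 (adjusted p = 0.0993) or the D2 library 3 (adjusted p = 0.0747). The list had an adjusted p of 0.0144, and an adjusted p of 0.994 with an estimated correlation. The spermatogonia list, with 12 members, had an adjusted p of 0.824. Among its members Sall4 stood at 45.8 ± 2.0 against 55.1 ± 4.5 CPM. Of 16 histocompatibility members 2 were lower in B6, H2-Aa at 0.950 ± 0.091 against 3.63 ± 0.59 CPM and H2-T3 at 1.38 ± 0.69 against 3.85 ± 0.23 CPM, and the list had an adjusted p of 0.397.

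**Figure D1:**
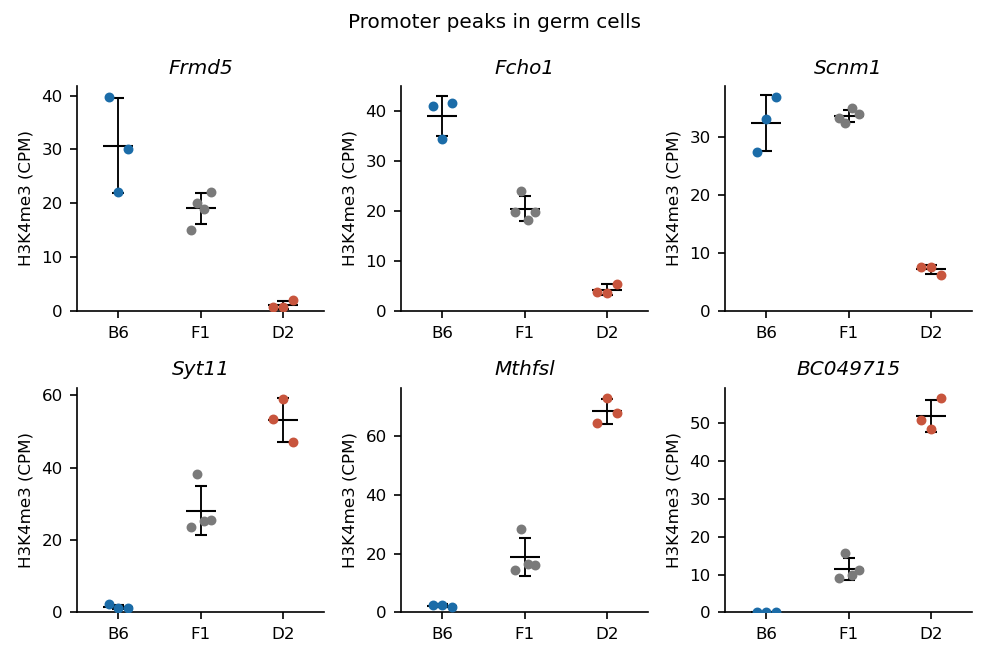
H3K4me3 in CPM (vertical axis, from 0) at 6 promoter peaks in germ cells of B6, F1 and D2, with 1 point per library and lines for the mean and SD. F1 sits between the parents at Frmd5 (19.1 CPM), Fcho1 (20.4) and Syt11 (28.1) and at the level of B6 at Scnm1 (33.7).

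The F1 hybrid was set against its parents to see whether a peak with both alleles in 1 nucleus sits at the mean of the parents. At the promoter of Wdr59, a regulator of amino acid signalling to mTORC1 (chromosome 8, 111520618 to 111523195, in an intron), F1 stood at 55.4 ± 2.7 CPM (n = 4) against 44.8 in B6 and 22.6 in D2 (n = 3 each), a log2 of 0.79 (SE 0.11) above the mean of the parents. Lower than that mean were intergenic peaks nearest Gm21915, by a log2 of -0.94, and nearest Sel1l, by -0.90, and an intron peak nearest Slc22a29, at 5.13 ± 0.63 CPM against 11.2 and 8.94, by -0.98. At the Frmd5 and Syt11 promoters F1 stood at 19.1 ± 2.9 and 28.1 ± 6.7 CPM, between the parents, and at Fcho1 at 20.4 ± 2.5.

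F1 differed from the mean of the parents, taken on the log2 scale, at 1070 peaks, 870 higher and 200 lower. The direction depended on the scale: against the mean of the parents on linear CPM, limma called 381 peaks, 37 higher and 344 lower, with 186 peaks in both counts. The stricter filter left 601. F1 differed from B6 at 3144 peaks (1874 higher in F1, 1270 lower) and from D2 at 3938 (1776 higher, 2162 lower). Without the B6 library B63 the B6 count was 6990 and the majority was lower in F1 (2243 higher, 4747 lower). The B6 count was 1574 without B64, 2075 without F1 library 3 and 1607 with the stricter filter, and the D2 count was 1886 with that filter. With replicate number as a block the D2 count was 3374.

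The BXD panel was used to ask whether peaks that differ between the founders also vary among their inbred descendants. For founder-differential peaks the median ratio of the variance between 61 strains to the variance between libraries of 1 strain was 1.94, against 0.904 for 9712 unchanged peaks matched on level. The within-strain part rested on 7 strains with 15 libraries. A permutation test of the peak classes gave p = 1e-05, the smallest that its permutations can give, but it treats peaks as independent, which they are not. With antibody lot regressed out the ratios were 1.96 and 0.868. Each of the 15 libraries of repeated strains was most like another library of its own strain over 4823 locally associated peaks (r across peaks 0.673 to 0.931, against a median of -0.021 between strains, where peaks are not independent replicates). Antibody lot went with 37751 of 66942 peaks (17861 higher and 19890 lower in lot 2557645), in a comparison of 28 strains with 32 others, so it was removed from each peak before strains were compared. The shallowest libraries, of BXD84, BXD83 and BXD56 (1.87, 2.13 and 2.23 M), were all of lot 2557645. Lot was thus not separated from strain or depth.

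Of the 11631 founder-differential peaks 4823 (41.5%) followed neighbouring peaks on their own chromosome across strains, within 10 Mb. Of 6410 unchanged peaks 3.76% did. The marker peaks, 4661 in number, were picked from these same founder-differential peaks and strains for lying near their best bin. Unchanged peaks could not be markers, so both shares are not a like comparison. The call threshold was set so that a mean of 582 of the 11631 peaks pass per permutation of the strains, local or distal. Local peaks included Frmd5, Fcho1, Apoa2 and Zfp429, and in 4792 of them strains with B6-like neighbours were high where B6 was high. Syt11 and Zfp960 were local but ran against the founders. Strains with B6-like neighbours were high at Syt11 (r = 0.847), where B6 was low, and low at Zfp960 (r = -0.501), where B6 was high. Within the strains of lot 2557645 alone 3752 peaks were local and within those of lot 2746331 4226.

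On other chromosomes 5269 founder-differential peaks (45.3%) followed a bin, and so did 43.2% of unchanged peaks. Each peak had 1 best bin, so a local peak could not be distal. Local were 4823 of the 11631 founder-differential peaks but 241 of the 6410 unchanged ones. Both distal shares are thus not a like comparison. In the designed scan the bin with the largest number was on chromosome 9, 25 to 30 Mb, with 1168 peaks, 1093 of them higher in B6, and 628 unchanged peaks. An intron peak of Cfap299 on chromosome 5 (98568415 to 98570469) followed it with r = 0.959 and a rank correlation of 0.928 across 61 strains (permutation p = 1e-05 each, the smallest that the permutations can give, for a peak chosen for its r). The r was 0.943 without the 2 strains farthest from the median, 0.919 among 28 strains of lot 2557645 and 0.971 among 32 strains of lot 2746331. Scans run anew placed 671 peaks at this bin in lot 2557645, 0 in lot 2746331 and 0 with ranks. Chromosome 15, 65 to 70 Mb, gathered 628 peaks and 226 unchanged ones (821, 2343 and 1622 peaks in these scans), and chromosome 13, 60 to 65 Mb, 608 peaks, 537 lower in B6, and 111 unchanged ones (226, 377 and 714). Chromosome 1, 75 to 80 Mb, gathered 594 peaks and 379 unchanged ones (410, 445 and 171), but 2688 and 1191 when at least 8 marker peaks per bin were required. Chromosome 10, 35 to 40 Mb, with 3 marker peaks, gathered 375 peaks and 1 unchanged one, and 0 peaks in each of these scans.

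A setting chosen after seeing these data removed 5 components of variation estimated from other unchanged peaks and asked for 8 marker peaks per bin. It left 2340 distal peaks (20.1%) against 14.6% of unchanged peaks. Local shares were 45.9% and 7.68%, so these distal shares too are not a like comparison. The chromosome 9 and 15 bins, with 1 and 4 marker peaks left, could not be tested in it, and with 5 components removed and at least 3 marker peaks per bin chromosome 15 held 26 peaks against 4 unchanged ones. Chromosome 13, 60 to 65 Mb, held 418 peaks, 174 higher in B6 and 244 lower, against 82 unchanged peaks. The peaks with the largest r at chromosome 13 included an intergenic peak nearest Kdr, a receptor for vascular endothelial growth factor (chromosome 5, 75807839 to 75809747), higher in B6 by 3.10 on the log2 scale, an intron peak of Schip1, higher by 4.20, and an intergenic peak nearest Vps54, higher by 3.85. The 5 Mb bin from 110 Mb on chromosome 12 gathered 238 peaks, 234 of them lower in B6, against 2 unchanged peaks, but 15 in the designed scan, 2 in lot 2557645 alone and 166 in lot 2746331 alone. It held 141 when only the number of marker peaks was raised and 214 when only the components were removed. Among the 238 were intergenic peaks nearest Marcks, with a log2 of -1.49, nearest Gbe1, the glycogen branching enzyme, with -3.37, and nearest Celf4, an RNA-binding protein, with -4.03. Strains fell into separate high and low sets at the chromosome 12 and 13 bins, so no r over all strains is given for their peaks. In the added setting the neighbouring bins of chromosome 13 gathered 190 peaks against 72 unchanged ones (55 to 60 Mb) and 150 against 19 (65 to 70 Mb). F1 and stem cell values were not taken at these neighbours. The distal count was 3229 in strains of lot 2557645 alone and 2226 to 3140 over 8 settings with 1 to 10 components removed.

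**Figure D2:**
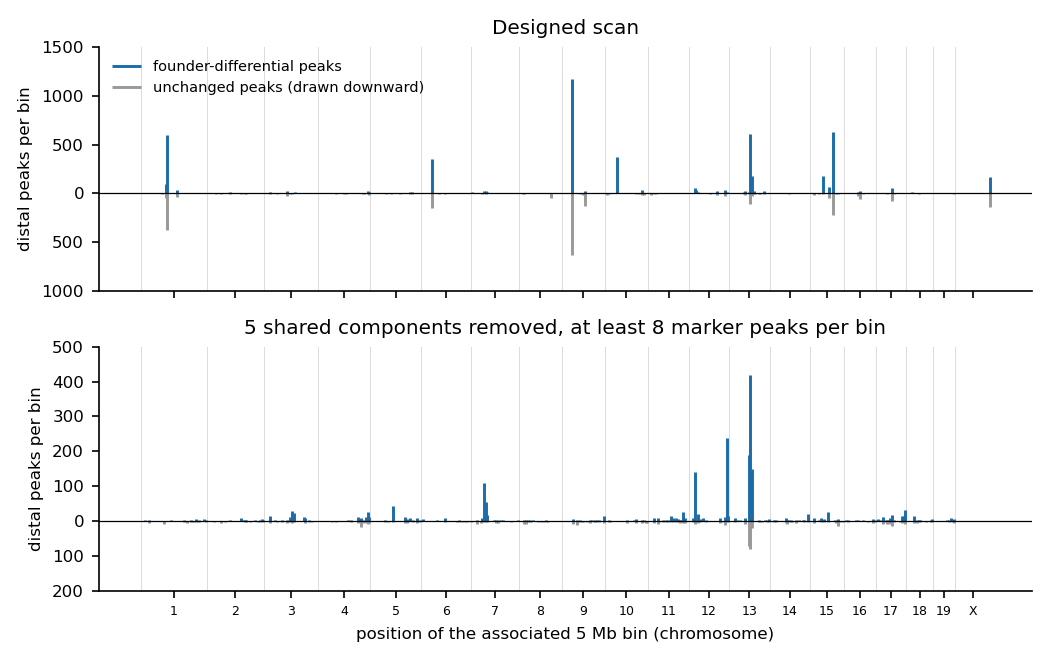
Number of distal peaks per 5 Mb bin (vertical axis) along the chromosomes, with founder-differential peaks drawn upward and unchanged peaks downward, in the designed scan and with 5 components removed. The bars at chromosome 9 (1168 peaks) and 15 (628) stand over 628 and 226 unchanged peaks. Both bins have too few marker peaks to be tested in the lower panel, where the tallest bars are at chromosome 13 (418) and chromosome 12 (238).

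Hepatocytes of B6 and D2 were compared in the same way. Erbb4, a receptor tyrosine kinase for neuregulins (chromosome 1, 69103580 to 69109195, in an intron), stood at 119 ± 6.2 CPM in B6 and 3.19 ± 0.94 in D2 (n = 3 each), a log2 difference of 5.18 (SE 0.26) with an adjusted p of 2.9e-09. Fggy, a carbohydrate kinase gene, stood at 49.3 ± 1.4 against 3.05 ± 0.91 CPM and Robo1, an axon guidance receptor, at 56.9 ± 5.0 against 7.80 ± 1.5 CPM. Cyp3a16, a cytochrome P450, stood at 35.6 ± 4.0 CPM in B6 with no D2 read, at least 436-fold higher, with 13.3 CPM in BXD75 and 4.72 in BXD87. Of 16 hepatocyte peaks with no D2 read 14 had neither of these lines low, and 16 were found on 1 genome alone. Higher in D2 were Adra1d, an alpha-1 adrenergic receptor, at 64.2 ± 7.0 CPM against 3.09 ± 0.99 in B6, Mrap2, a melanocortin receptor accessory gene, at 29.7 ± 0.84 against 1.28 ± 0.46, and Tlr6, a Toll-like receptor, at 29.7 ± 7.1 against 4.54 ± 0.56. Cyp2c39, a retinoic acid hydroxylase, stood at 241 ± 14 CPM in D2 and 37.6 ± 1.8 in B6.

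Genes of xenobiotic metabolism went both ways in hepatocytes: of 33 measured members 3 were higher in B6 and 5 lower (4 and 6 with p values adjusted over the list alone, list adjusted p = 0.158). Cyp2d9 stood at 11.8 ± 1.3 against 52.1 ± 5.9 CPM, Cyp4a10, a fatty acid hydroxylase, at 62.6 ± 15 against 29.6 ± 2.9 CPM, Gstm3, a glutathione transferase, at 17.3 ± 4.2 against 27.7 ± 1.9 CPM and Ahr, the aryl hydrocarbon receptor, at 206 ± 14 against 161 ± 10.2 CPM. Of 23 interferon response promoters 7 were lower in B6 and 1 higher (10 and 1 with p values adjusted over the list alone). Ifit3 stood at 2.83 ± 0.46 against 9.71 ± 2.8 CPM, Ifi27 at 28.5 ± 1.1 against 50.9 ± 10.1 CPM and Ifi44 at 26.0 ± 3.0 against 45.5 ± 4.3 CPM, while Gbp6 was higher at 37.6 ± 2.0 against 24.9 ± 1.3 CPM. The list adjusted p was 4.4e-07, and the adjusted p was 0.570 with an estimated correlation. Of 10 histocompatibility members 1 was lower in B6, H2-T24 at 30.2 ± 0.99 against 57.5 ± 5.4 CPM (3 with p values adjusted over the list alone, of which Psmb8 and Tap2 share 1 peak). That list had an adjusted p of 0.0135, and an adjusted p of 0.570 with an estimated correlation.

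Markers of the hepatocyte itself had an adjusted p of 0.737 over 28 members, with Alb, the albumin gene, at 122 ± 34 against 155 ± 47 CPM. edgeR called 0 of them, with 0 higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 0 higher and 0 lower. Among markers of liver cells that are not hepatocytes, Stab2, a scavenger receptor of sinusoidal endothelium, stood at 10.2 ± 2.1 against 54.5 ± 21 CPM and was the 1 of 7 that was called, while the list had an adjusted p of 0.217. In all 4593 of 29137 hepatocyte peaks differed between the founders, 2144 higher in B6 and 2449 lower, or 7.37% of promoter peaks and 20.9% of others. With replicate number as a block 4678 differed. Of the 4593 calls 919 were peaks found on the reference genome alone and 1081 on the second genome alone.

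BXD75 and BXD87, a pair of inbred lines with the same founders, differed at 1425 hepatocyte peaks, 827 higher in BXD75 and 598 lower. Adra1d stood at 85.7 ± 15 CPM in BXD75 and 3.58 ± 1.6 in BXD87 (n = 3 each), a log2 difference of 4.53 (SE 0.24), and Fggy at 35.8 ± 3.1 against 4.19 ± 1.4 CPM. Cyp3a44, a cytochrome P450, stood at 55.7 ± 5.1 against 14.5 ± 4.4 CPM, Sult3a1, a sulfotransferase, at 98.6 ± 22 against 29.8 ± 7.9 CPM, and C6, a complement component, at 28.9 ± 8.4 against 10.3 ± 0.93 CPM. Higher in BXD87 were Hsd3b2, a steroid dehydrogenase, at 95.6 ± 13 against 21.9 ± 4.7, Sult1e1, the estrogen sulfotransferase, at 29.6 ± 5.1 against 7.61 ± 1.0, and Vipr2, a receptor for vasoactive intestinal peptide, at 28.0 ± 1.1 against 5.56 ± 2.6. With replicate number as a block 1530 peaks differed. In fits of these lines alone BXD75 libraries 1 and 2 with BXD87 library 1 against the rest called 4177 peaks, against 1187 for the lines, and BXD87 libraries 2 and 3 were nearly alike (chi-square per degree of freedom 1.19, against 8.70 and 11.8 from library 1).

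Of 33 xenobiotic metabolism promoters 2 were lower in BXD75 than in BXD87, among them Cyp3a11 at 76.9 ± 21 against 123 ± 11 CPM (3 with p values adjusted over the list alone). The Cyp3a11 call was lost without BXD87 library 1 (adjusted p = 0.0902) or 2 (adjusted p = 0.0585). The list had an adjusted p of 1.8e-05, and an adjusted p of 0.994 with an estimated correlation. The hepatocyte list had an adjusted p of 0.00283 and a median log2 of -0.12, with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 87.5 ± 8.3 against 110.1 ± 7.4 CPM, and an adjusted p of 0.994 with an estimated correlation. The interferon response list had a median log2 of 0.12 with an adjusted p of 0.00703, and an adjusted p of 0.994 with an estimated correlation. In both the hepatocyte and the interferon list edgeR called 0 members, also with p values adjusted over the list alone, and DESeq2 called 0. Markers of other liver cells had an adjusted p of 0.462 and histocompatibility genes of 0.588.

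Of the hepatocyte peaks called between BXD75 and BXD87 1074 (75.4%) were also called between B6 and D2. Of these, 593 went the same way, with BXD75 like B6, and 481 the opposite way, where independence of both calls would give 111 and 114. With replicate number as a block 1117 were shared, 619 the same way and 498 the opposite way. Fggy was among the first, at 35.8 ± 3.1 CPM in BXD75 and 4.19 ± 1.4 in BXD87, and Adra1d among the second, with BXD75 at the level of D2. Hsd3b2 was high in BXD87 and D2 (92.6 CPM) and low in BXD75 and B6 (19.3 CPM). Of the founder calls 53.6% were nearer B6 in BXD75 and 50.9% in BXD87. The directions parted: of calls higher in B6 73.0% and 67.1% were nearer B6, and of calls higher in D2 36.6% and 36.8%, so that both lines were more often near the higher founder. Normalisation factors were 0.929 to 0.952 in the founder libraries and 1.04 to 1.095 in the line libraries. Whether this difference between the sets bears on the positions was not tested.

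Cardiomyocytes of B6 and D2 were compared to find the peaks that differ in heart muscle. Usp13, a deubiquitinase (chromosome 3, 32816788 to 32828654, in an intron), stood at 123 ± 3.9 CPM in B6 and 19.0 ± 1.9 in D2 (n = 3 each), a log2 difference of 2.70 (SE 0.11) with an adjusted p of 6.3e-09. Elk3, an ETS transcription factor, stood at 289 ± 10.5 against 49.7 ± 6.4 CPM. Higher in D2 were Nid1, a basement membrane protein, at 115.2 ± 14 CPM against 0.47 ± 0.13 in B6, Cntfr, the receptor for ciliary neurotrophic factor, at 54.8 ± 5.4 against 5.65 ± 1.4, Etnk2, an ethanolamine kinase, at 79.7 ± 14 against 22.7 ± 6.0, and the histocompatibility gene H2-T23 at 76.6 ± 7.5 against 22.8 ± 4.9. At Usp13 and Elk3, BXD75 and BXD87 stood near B6, at 117 and 147 CPM and at 289 and 299 CPM, and at Nid1 near D2, at 102 and 91.2 CPM.

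Of 30 cardiomyocyte promoters 13 were higher in B6 than in D2 (22 with p values adjusted over the list alone) and the list median was 0.45 on the log2 scale. Nkx2-5 and Tbx5, transcription factors of the heart, stood at 223 ± 24 against 131 ± 3.4 CPM and 172 ± 8.7 against 111 ± 3.8 CPM, Kcnj2, an inward rectifier potassium channel, at 181 ± 26 against 90.1 ± 9.3 CPM, and Cox6a2, a cytochrome oxidase subunit of striated muscle, at 66.3 ± 4.1 against 40.4 ± 1.2 CPM. The list had an adjusted p of 3.0e-13, and an adjusted p of 0.0668 with an estimated correlation. The D2 libraries, with 2.62 to 4.10 M reads, were also the ones that stood apart: of the 1551 founder calls 1361 (87.7%) were nearer B6 in both BXD75 and BXD87. Markers of heart cells that are not myocytes had an adjusted p of 0.737 over 14 members, with Tcf21, of cardiac fibroblasts, at 49.0 ± 4.4 against 63.6 ± 3.7 CPM. Their median log2 was -0.115, against -0.047 for all promoters, with 0 higher and 3 lower at an unadjusted p under 0.05. Interferon response genes had an adjusted p of 0.737, and of 12 histocompatibility members 1, H2-T23, was called (adjusted p = 0.264).

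In all 1551 of 23809 cardiomyocyte peaks differed between the founders, 967 higher in B6 and 584 lower, and 1007 of them lay at a promoter, or 8.66% of promoter peaks and 4.47% of others. Single libraries moved this count: it was 533, 3679 or 545 without B6 library 1, 2 or 3 and 704, 502 or 708 without D2 library 1, 2 or 3. It was 2536 by DESeq2, 3347 with only the founders in the fit, 831 with replicate number as a block, and 555 (457 higher, 98 lower) with all libraries thinned to the smallest total. Of the 1551 calls 637 were peaks found on the reference genome alone and 57 on the second genome alone. Whether this bears on the majority higher in B6 was not tested.

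BXD75 and BXD87 cardiomyocytes differed at 126 peaks, 76 higher in BXD75 and 50 lower. Hdhd3, a hydrolase-like gene, stood at 140.0 ± 20.1 against 67.7 ± 3.0 CPM (n = 3 each), with D2 at 139.5 CPM and B6 at 57.0, a log2 difference of 1.05 (SE 0.10) with an adjusted p of 2.2e-04. Tmem100, a membrane protein of endothelium, stood at 106 ± 20 against 50.4 ± 6.9 CPM and Rab6b, a Golgi GTPase, at 49.7 ± 12 against 15.6 ± 5.2 CPM, calls lost when only these lines were in the fit (adjusted p = 0.0549 and 0.0793). Housekeeping promoters had a median log2 of -0.08 in this comparison, against 0.08 for all promoters. Their list had an adjusted p of 0.0398 by camera, and an adjusted p of 0.864 with an estimated correlation, with 0 members called higher and 0 lower. BXD75 library 1 stood apart from 2 and 3 (chi-square per degree of freedom 17.5 and 12.2, against 3.82). Cardiomyocyte promoters were lower in BXD75: the list median was -0.31 on the log2 scale over 30 members, 17 fell with p values adjusted over the list alone, and the list had an adjusted p of 4.6e-22, and an adjusted p of 0.0306 with an estimated correlation. Over all peaks 1 member was called, Fabp3, a fatty acid binding protein, at 144 ± 5.4 against 191 ± 4.3 CPM, a call lost without BXD75 library 2 or 3 or any BXD87 library (adjusted p = 0.0520, 0.144, 0.159, 0.114 and 0.201). Pln, the phospholamban gene, stood at 83.8 ± 22 against 152 ± 11 CPM and Atp2a2, the calcium pump it regulates, at 132 ± 26 against 195 ± 15 CPM.

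Markers of other heart cells had an adjusted p of 0.981 between the lines, with Wt1, of the epicardium, at 119 ± 19.7 against 90.2 ± 4.2 CPM, interferon response genes of 0.363 and histocompatibility genes of 0.588. The markers of other heart cells had a median log2 of 0.148 and a mean of 0.056, against a median of 0.078 for all promoters. At an unadjusted p under 0.05, 3 of them were higher and 0 lower. The count of 126 was 504 without BXD75 library 2, 77 without BXD75 library 3, and 57 or 47 without BXD87 library 1 or 3. It was 461 by DESeq2 (210 higher, 251 lower), 27 with only these lines in the fit, 72 with replicate number as a block and 14 with all libraries thinned. The BXD87 libraries were the deepest of the cardiomyocytes. Of the peaks called between the lines 45 were also called between the founders, 10 the same way and 35 the opposite way, against 4.31 and 3.89 under independence. Hdhd3 was among the 35. That count was 137 without BXD75 library 2, 25 or 26 without B6 library 1 or 3, 28, 28 or 27 without D2 library 1, 2 or 3, 29 without BXD75 library 3, 26 or 22 without BXD87 library 1 or 3, 198 by DESeq2, 14 at an adjusted p under 0.01, 16 with only the groups compared in each fit, 25 with replicate number as a block and 10 with all libraries thinned.

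Embryonic stem cells of B6 and D2 differed at 20566 peaks, 9938 higher in B6 and 10628 lower, or 12.5% of promoter peaks and 35.5% of others. Of these calls 5152 were peaks found on the reference genome alone and 5019 on the second genome alone. Nod1, a sensor of bacterial peptidoglycan (chromosome 6, 54950864 to 54973729, in an intron), stood at 185 ± 3.3 CPM in B6 and 26.5 ± 2.4 in D2 (n = 3 lines each), a log2 difference of 2.81 (SE 0.13) with an adjusted p of 8.9e-13. Bahcc1, a chromatin reader, stood at 192 ± 11 against 25.3 ± 6.1 CPM and Stard3nl, of late endosomes, at 66.4 ± 0.39 against 9.52 ± 3.0 CPM. Zfp429 stood at 18.9 ± 1.1 CPM in B6 with no D2 read, at least 558-fold higher, with 19.6 CPM in BXD75 and 13.1 in BXD87. Of 44 stem cell peaks with no D2 read 36 had neither of these lines low, and 42 were found on 1 genome alone. Higher in D2 were Syt11, at 21.1 ± 5.8 CPM against 0.321 ± 0.26 in B6 at 1 promoter peak and 37.4 ± 5.9 against 1.96 ± 0.11 at another, Cntfr at 16.7 ± 4.1 against 1.03 ± 0.23, and Acsm4, an acyl-CoA synthetase, at 20.5 ± 2.2 against 2.2 ± 0.28. An intergenic peak nearest Fcgr3, an Fc receptor gene, stood at 83.2 ± 4.7 against 1.81 ± 0.42 CPM.

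Of 17 histocompatibility genes of stem cells, with 16 promoter peaks, 7 were lower in B6 and 2 higher. H2-Eb1 stood at 27.9 ± 1.6 against 65.1 ± 17 CPM and H2-T24 at 1.18 ± 0.39 against 4.52 ± 2.4 CPM, while H2-D1 was higher, at 14.0 ± 1.2 against 6.50 ± 1.1 CPM. The list had an adjusted p of 0.0472, and an adjusted p of 0.994 with an estimated correlation. Among 24 naive pluripotency members 1 was called, Klf5, at 177 ± 14 against 219 ± 30.3 CPM, a call lost without B6-139 or B6-146 or D2-203 or the D2 line with the highest number (adjusted p = 0.0857, 0.0860, 0.0903 and 0.0721). That list had an adjusted p of 0.636. Of 23 lineage differentiation members 3 were lower in B6, among them Elf5, a factor of the trophoblast, at 5.90 ± 0.58 against 9.21 ± 1.3 CPM (list adjusted p = 0.148). Interferon response genes, 2 higher and 2 lower of 17, had an adjusted p of 0.820. Of all peaks called between the founders the majority was higher in B6 without B6-146 (8812 and 8644) or D2-203 (8717 and 8436). With every library of a line as its own replicate 31493 peaks differed between the founders, and 19 genes of the 2-cell-like state had too few promoter peaks for a test.

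BXD75 and BXD87 stem cells differed at 14628 peaks, 6680 higher in BXD75 and 7948 lower. Obox6, an oocyte-specific homeobox gene, stood at 34.7 ± 1.3 CPM in BXD75 and 2.46 ± 0.47 in BXD87 (n = 5 lines each), a log2 difference of 3.83 (SE 0.11), and Crxos, a homeobox gene nearby, at 54.7 ± 3.3 against 4.93 ± 0.22 CPM. Nod1 was lower in BXD75, at 38.3 ± 4.9 against 203 ± 23 CPM, as was Prkca, a protein kinase C, at 14.7 ± 1.4 against 59.5 ± 4.2 CPM. Of the 17 histocompatibility genes 5 were lower in BXD75 and 1 higher (7 and 1 with p values adjusted over the list alone): H2-Eb1 stood at 41.0 ± 5.6 against 91.2 ± 13 CPM and H2-T3 at 11.8 ± 0.60 against 20.9 ± 1.8 CPM. The list had an adjusted p of 8.8e-07, and an adjusted p of 0.570 with an estimated correlation. Of 24 naive pluripotency genes 1 was higher and 1 lower, the latter Lin28b, which blocks let-7 processing, at 15.4 ± 1.4 against 22.3 ± 1.5 CPM (list adjusted p = 0.588), and of 23 lineage genes 3 were higher and 1 lower, with Elf5 at 6.69 ± 0.92 against 10.6 ± 1.5 CPM and Meox1, of the somites, at 4.75 ± 1.2 against 2.06 ± 0.66 CPM (list adjusted p = 0.737). Of 17 interferon response genes 3 were higher and 2 lower, with Ifit2 at 7.34 ± 0.49 against 4.29 ± 0.47 CPM and Oas1g at 22.4 ± 1.6 against 31.5 ± 6.5 CPM (list adjusted p = 0.737).

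Of the stem cell peaks called between the lines 7598 (51.9%) were also called between the founders, 5541 the same way and 2057 the opposite way, against 2245 and 2232 under independence. At an adjusted p under 0.01 in both comparisons 4384 were shared. Nod1 had BXD75 at the level of D2, and Prkca had BXD75 at the level of B6 (15.5 CPM) and BXD87 at that of D2 (67.5 CPM). Of the founder calls 54.8% were nearer B6 in BXD75 (58.0% of those higher in B6 and 51.8% of those higher in D2) and 36.9% in BXD87 (42.5% and 31.6%).

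**Figure D3:**
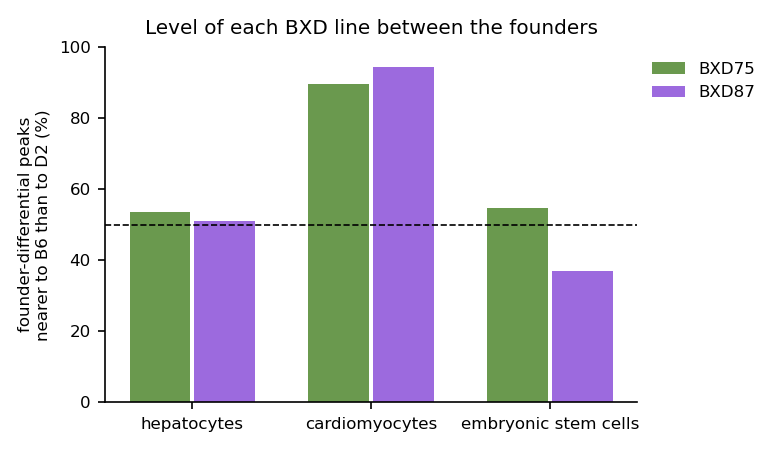
Percent of founder-differential peaks at which BXD75 or BXD87 stood nearer to B6 than to D2 (bars from 0), by cell type, with a dashed line at 50%. Cardiomyocytes stand at 89.6% and 94.3%, hepatocytes at 53.6% and 50.9%, and stem cells at 54.8% and 36.9%. The bars pool both directions, and in hepatocytes calls higher in B6 stood at 73.0% and 67.1% and calls higher in D2 at 36.6% and 36.8%.

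The founder difference was then compared between cell types at 2942 peaks matched in all 4 sets, and it depended on the cell type at 242 of them. In an intron of Syne3, a gene of the nuclear envelope (chromosome 12, 104978015 to 104979650), hepatocytes of B6 stood above D2 at 7.75 ± 0.88 against 0.334 ± 0.11 CPM, a log2 of 4.56 (SE 0.31), and germ cells below, at 0.987 ± 0.41 against 6.21 ± 1.1 CPM, a log2 of -2.47 (SE 0.25). Cardiomyocytes and stem cells differed there by -0.14 (SE 0.18) and -0.03 (SE 0.16) (adjusted p of the dependence 4.8e-16). At Robo1 the log2 difference was 2.86 (SE 0.18) in hepatocytes, -0.70 (SE 0.19) in cardiomyocytes and 0.00 (SE 0.16) in germ cells (adjusted p 7.0e-14). At Mturn it was 3.71 (SE 0.20) in germ cells and 4.24 (SE 0.23) in hepatocytes against 1.15 (SE 0.21) in cardiomyocytes (adjusted p 4.4e-13), and at an intergenic peak nearest Aqp11, a water channel, 3.03 (SE 0.17) in hepatocytes and -0.02 (SE 0.15) in germ cells (adjusted p 7.0e-13).

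By pairs of cell types, hepatocytes and cardiomyocytes differed at 171 of these peaks, hepatocytes and stem cells at 122, cardiomyocytes and stem cells at 107, germ cells and hepatocytes at 72, germ cells and stem cells at 45 and germ cells and cardiomyocytes at 19. Germ cells differ from the others also in library kit and, for these founders, antibody lot, which cannot be told apart from cell type. They came from males and the hepatocytes and cardiomyocytes from females, and the sex of the stem cell lines is not given. Without germ cells, over 4877 matched peaks, 555 differed. The count of 242 was 390 without germ cell library B62 and 425 without cardiomyocyte B6 library 2, and 21 of 98 matched peaks differed when overlap had to reach 80%.

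**Figure D4:**
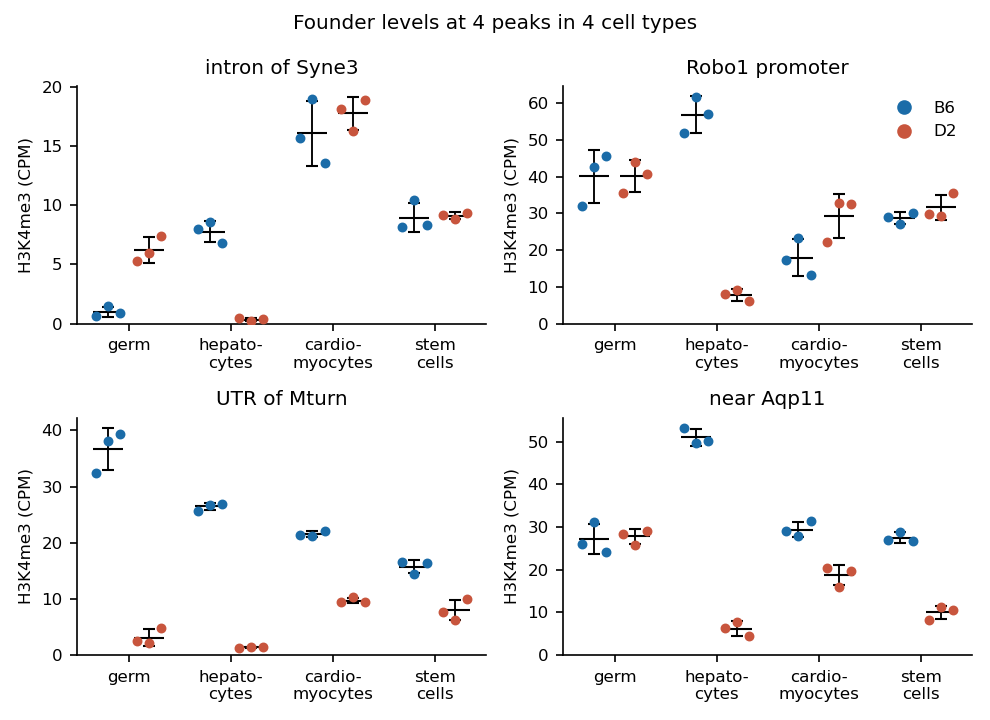
H3K4me3 in CPM (vertical axis, from 0) of B6 and D2 in 4 cell types at the peaks in Syne3, Robo1 and Mturn and near Aqp11, with 1 point per replicate and lines for the mean and SD. At Syne3 B6 is above D2 in hepatocytes and below it in germ cells.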

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

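The tests of peaks without reads and of variation shared by the panel, and the counts over other splits of the samples except those for F1 against the mean of the parents and for cell type, were chosen only after the result was seen. Of 92 sets of 4 to 10 samples tested for 1 value far from the others 9 stood out, where chance alone gives about 1 in 20, or 4.6.

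Most of the values far from their group lay in BXD87 stem cell line I. Its level was far above the other 4 BXD87 lines at Nod1 (244 against 190.0 to 198 CPM, gap over range 0.854), H2-Eb1 (113 against 82.0 to 90.7, 0.719), H2-T24 (7.13 against 2.85 to 3.96, 0.741), Oas1g (43.1 against 27.8 to 29.3, 0.907) and Zfp874a (30.3 against 27.0 to 27.6, 0.813). Its normalisation factor was far below theirs (0.943 against 1.00 to 1.02, 0.712). BXD87 line M was far above the others at the peak near Mtus1 (0.678 against 0.0560 to 0.204 CPM, 0.762). BXD75 line Q was far above at the peaks near Dnajc5b (1.07 against 0.497 to 0.646 CPM, 0.738) and Olfr1329 (2.57 against 1.54 to 1.79 CPM, 0.752). The limit for 5 samples is 0.71.

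At 4 peaks the founder difference itself differed between cell types by the test of that difference: Syne3 (adjusted p = 4.84e-16), Robo1 (6.96e-14), Mturn (4.42e-13) and the peak near Aqp11 (6.97e-13).

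Germ cell peaks with no read in 1 founder numbered 125, of which 70 had none in D2 and 55 none in B6. If a founder allele without the peak were inherited, about as many BXD strains as carry that allele would be low, but 15 to 45 low strains were seen in 14.4% of the peaks (18), which argues against this for most of them. In 79.2% (99) at most 3 of the 61 strains stood below 10% of the founder with reads, a pattern consistent with reads of 1 founder having been counted on a genome where the region has no place. F1 stood at a median of 0.83 of B6 at peaks empty in D2 and 0.507 of D2 at peaks empty in B6. Copies that D2 or B6 truly lack at some of these places stay open.

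BXD100 and BXD43 were the most alike of all pairs of different strains (r = 0.542 across 4823 local peaks, the next pair 0.429, the 99th percentile 0.263). A mixed library would hold both alleles at many places. BXD100 stood between the founder levels in 5.04% of 238 bins and BXD43 in 4.62%, ranks 37 and 45 of 61, while mixtures computed from BXD43 and each other strain had a median of 43.7%. The highest share, 21%, was in BXD75, above the lowest of the computed mixtures (18.5%), and whether its library is mixed was not tested. A mixed library is argued against for BXD100 and BXD43, and shared ancestry of the lines stays open and was not tested.

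Among the distal bins, the chromosome 9 bin at 25 to 30 Mb took 1.025 times the share of founder-differential peaks that it took of unchanged ones. The shares are of all tested peaks, and local peaks (41.5% of founder-differential and 3.76% of unchanged ones) could not be distal. This lowers the quotients. At chromosome 9 the quotient thus does not decide whether variation shared by the panel, whatever the founder difference, is the whole account. At chromosome 15, 65 to 70 Mb, the quotient was 1.53, where such variation stays open. At chromosome 13, 60 to 65 Mb, it was 3.02, which argues against such variation as the whole account.

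Other splits of the samples were counted for each comparison, with only the groups compared in each fit except for F1 against the mean of the parents, cell type and antibody lot, so that those real counts differ from the reported ones. In stem cells BXD75 against BXD87 1 of 24 splits called as many peaks, the real one (17013, highest other 0). In F1 against B6 it was 1 of 24 (2883, highest other 0) and in F1 against D2 1 of 24 (4671, highest other 458). In F1 against the mean of the parents it was 1 of 21 (1070, highest other 605), for cell type 1 of 50 (242, highest other 67) and for antibody lot 1 of 21 (37751, highest other 0). These are the smallest shares that so many splits can give, and they were not adjusted over the comparisons. For the mean of the parents and for cell type the other splits also mixed the founders, so they do not test that difference alone. The shares are low but do not exclude chance assignment. The other comparisons allow only 10 splits, too few for a share under 0.05. The real split called 8606 peaks in germ cells B6 against D2, 4774 in hepatocytes, 3347 in cardiomyocytes and 14503 in stem cells, and 27 in cardiomyocytes BXD75 against BXD87, with a highest other of 0 and 1 such split in each. In hepatocytes BXD75 against BXD87 the real split called 1187, and 2 of 10 splits called as many: BXD75 libraries 1 and 2 with BXD87 library 1 against the rest called 4177, which points to a structure of these samples other than the line.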

How the results depend on the processing

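Alternatives with 5 components or others removed, thinned or summed libraries and other settings for the shared calls were chosen after seeing the data. Of 134 counts with 1 library left out 109 stayed within 1.5 times the reported count and 25 moved, and of 148 results under other alternatives 104 kept their call or stayed within 1.5 times. Of 271 named results 204 kept their call under all alternatives run for them, 67 lost it in some and 0 changed sign. The cause was not tested, except that thinning and a filter on low counts leave fewer reads or peaks. Depth limits the cardiomyocyte counts, which fell with thinned libraries, and was not tested elsewhere. Removing peaks by input depth was not run, since there are no input counts.

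With 1 library left out the counts ranged from 7639 to 16222 in germ cells B6 against D2, 786 to 1211 in F1 against the mean of the parents, 1574 to 6990 against B6, 2855 to 3554 against D2, 3602 to 4617 in hepatocytes B6 against D2, 1064 to 1473 in BXD75 against BXD87, 502 to 3679 and 47 to 504 in cardiomyocytes, 14707 to 23603 and 11703 to 14773 in stem cells, 162 to 425 for cell type, and for shared calls 885 to 1041 in hepatocytes, 22 to 137 in cardiomyocytes and 6274 to 7850 in stem cells.

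The stricter filter gave 5028 in germ cells B6 against D2, 601 in F1 against the mean of the parents, 1607 against B6 and 1886 against D2, and linear CPM 381 for F1. Cardiomyocytes B6 against D2 gave 2536 by DESeq2, 3347 with only the founders, 831 with the replicate block and 555 thinned. BXD75 against BXD87 gave 461, 27, 72 and 14, and shared calls 198, 16, 25 and 10, with 14 at an adjusted p under 0.01. In stem cells every library as its own replicate gave 31493 and shared calls at an adjusted p under 0.01 numbered 4384. For cell type 80% overlap gave 21 and leaving germ cells out 555. Distal peaks numbered 3229 in lot 2557645 and, with 1, 3, 5 and 10 components removed, 3096, 3140, 2419 and 2383 with 3 marker peaks per bin and 2355, 2620, 2340 and 2226 with 8.

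With an estimated correlation the lists no longer called had adjusted p values of 0.791 (meiotic prophase), 0.994 (Sertoli and Leydig) and 0.386 (interferon) in germ cells, 0.570 (histocompatibility) and 0.570 (interferon) in hepatocytes B6 against D2, 0.994 (hepatocyte, xenobiotic, interferon) in BXD75 against BXD87, 0.0668 (cardiomyocyte) and 0.864 (housekeeping) in cardiomyocytes, and 0.994 and 0.570 (histocompatibility) in stem cells.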

Other observations

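The tests in distal bins at chromosomes 7, 12 and 13 were written before their results, except that the bin at chromosome 12, 15 to 20 Mb, and the limits for an allele difference and for the interval were added after the first 3 bins had been seen and the splits by direction and the draws of other peaks after the values were seen. Zinc finger genes, many of which encode KRAB repressors of transposable elements, had called members in all 4 cell types, but the list as a whole was called in none. Between B6 and D2 8 of 319 members were higher in B6 germ cells and 7 lower, 8 of 299 higher and 8 lower in hepatocytes, 19 of 292 higher and 2 lower in cardiomyocytes, and 33 of 310 higher and 7 lower in stem cells. Of all promoter peaks 4.4%, 7.37%, 8.66% and 12.5% were called in these comparisons. With p values adjusted over the list alone 6 and 2, 6 and 3, 21 and 2, and 23 and 6 passed. The list as a whole had adjusted p values of 0.172, 0.981, 0.172 and 0.0694. Zfp429, Zfp937 and Zfp960 promoters had no D2 read in germ cells, with Zfp937 at 5.09 ± 1.8 CPM in B6. Zfp729b stood at 37.6 ± 0.51 against 4.61 ± 0.23 CPM in hepatocytes, and Zfp775, at a peak shared with the promoter of Repin1, at 139.9 ± 15 against 54.0 ± 8.0 CPM in cardiomyocytes. Between BXD75 and BXD87 Zfp729b stood at 24.1 ± 2.9 against 4.46 ± 1.1 CPM in hepatocytes and Zfp658 at 16.4 ± 1.0 against 33.0 ± 1.7 CPM in stem cells, and the list had adjusted p values of 0.208, 0.462 and 0.981 in hepatocytes, cardiomyocytes and stem cells.

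Genes that write or erase H3K4 methylation had list adjusted p values between 0.621 and 0.951 over the comparisons. Members called were Kdm1b, a demethylase, lower in B6 hepatocytes (102 ± 5.0 against 129.7 ± 3.2 CPM, at a peak shared with the promoter of Tpmt and nearer to it), and in stem cells Kdm5b, another, higher in B6 than in D2 (223 ± 4.3 against 162 ± 39 CPM) and in BXD75 than in BXD87 (210.3 ± 11 against 155 ± 24 CPM). Of writer complexes Dpy30 was lower in B6 than in D2 stem cells (96.4 ± 3.7 against 112 ± 6.5 CPM) and Rbbp5 lower in BXD75 than in BXD87 (167 ± 12 against 208 ± 19 CPM). The first Kdm5b call was lost without B6-49 (adjusted p = 0.0532) or D2-173 (0.0868), the Dpy30 call without any line but D2-173 (0.0549 to 0.156), and the Rbbp5 call without BXD75 line A, F, N or Y or BXD87 line C or I (0.0503 to 0.0901). KRAB silencing cofactors had list adjusted p values between 0.737 and 0.981. Among them Dnmt3a, a de novo DNA methyltransferase, was higher in BXD75 than in BXD87 stem cells (35.8 ± 9.3 against 23.4 ± 3.1 CPM). Housekeeping genes had list adjusted p values between 0.621 and 0.984, except between BXD75 and BXD87 cardiomyocytes, where the median log2 was -0.08 with an adjusted p of 0.0398, and an adjusted p of 0.864 with an estimated correlation. Pgk1, a glycolytic enzyme, was higher in BXD75 than in BXD87 stem cells (78.9 ± 9.8 against 63.1 ± 2.2 CPM).

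A hypothesis is that the distal bins hold alleles that lower H3K4me3 at distant peaks and act in F1 as in the lower parent. On a scale of linear CPM with the lower parent at 0 and the higher at 1, F1 stood at a median of 0.395 over all founder-differential peaks. It stood at 0.335 for the peaks that follow chromosome 13, 60 to 65 Mb, 0.188 for the 5 Mb bin from 110 Mb on chromosome 12, 0.0440 for chromosome 7, 35 to 40 Mb, and 0.247 for chromosome 12, 15 to 20 Mb, with 0 of 10000 matched random sets as low at each, where the lowest random medians were 0.342, 0.369, 0.295 and 0.314. The peak sets come from the setting chosen after seeing the data. It put 108 peaks at chromosome 7 and 140 at chromosome 12, 15 to 20 Mb, against 21 and 50 in the designed scan. Random sets were drawn peak by peak, while the peaks of a bin were picked for varying together. The draws thus count related peaks as independent. They also held peaks that were local in the designed scan, where F1 stood at a median of 0.448 over 4781 peaks. The peaks of the bins were all distal. Draws from distal peaks alone were not made, so the random sets may overstate how far the bins lie from other distal peaks. Positions on the log2 scale were not taken. At chromosome 13 the directions parted: 0.247 for 174 peaks higher in B6, against 0.358 for all such peaks, and 0.414 for 244 peaks higher in D2 (resampled 95% interval 0.375 to 0.465), against 0.439, with 2025 of 10000 random sets as low. At chromosome 12, 15 to 20 Mb, it was 0.311 for 60 peaks higher in B6, with 139 of 10000 random sets as low, and 0.153 for 80 peaks higher in D2, with 0. Lower in B6 were 234 of 238 peaks at the chromosome 12 bin from 110 Mb and 107 of 108 at chromosome 7. Their values go with a lowering allele of B6. At chromosome 13 and at chromosome 12, 15 to 20 Mb, peaks went both ways, which would take lowering alleles of both founders. The values go with such an allele for peaks higher in B6 at chromosome 13 and for peaks higher in D2 at the other bin. For the opposite directions at these bins it stays open. Clusters of KRAB zinc finger repressors, such as that around Zfp429 near the chromosome 13 bin, are a candidate source that was not tested.

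If such an allele also acts in stem cells, BXD75 and BXD87 should differ there in the direction the germ cell panel predicts wherever they carry different alleles. Other founder-differential peaks, with the same numbers in each direction, gave a share of 49.7%, 49.7%, 50% and 50.2% for the 4 bins in the order below. Random draws from them take peaks as independent. The prediction takes the direction of each peak from the panel, so a match does not show that an allele lowers its peaks. At chromosome 12, 15 to 20 Mb, where the lines clearly differ, 100% of 17 matched stem cell peaks went the predicted way (exact 95% interval from 80.5%, which like the others takes peaks as independent), and 12 of 12 called ones, with 6 of 9 in hepatocytes (4 of 4 called) and 3 of 3 in cardiomyocytes, and 1 of 10000 random draws of the other peaks was as high (4 of 10000 among called ones), which is consistent with an allele that acts in germ cells and stem cells. At chromosome 13, 60 to 65 Mb, 52.4% of 105 did (interval 42.4 to 62.2%) and 26 of 38 called ones, with 4 of 7 in hepatocytes and 5 of 15 in cardiomyocytes, and 3156 of 10000 draws were as high (338 among called ones), which leaves it open. At the chromosome 12 bin from 110 Mb, 26.2% of 42 (interval 13.9 to 42.0%) and 2 of 11 called ones, and at chromosome 7, 35 to 40 Mb, 67.6% of 37 (50.2 to 82.0%) and 7 of 9 called ones did. BXD75 and BXD87 stood at 0.639 and 0.486 and at 0.723 and 0.881 there, on the scale given next, so they are not clearly different and the test decides nothing. The direction rests on the germ cell library of BXD75, which had the largest share of bins between the founder levels and, with the 10th percentile of the strains at 0 and the 90th at 1, B6 up, stood at 0.812 at chromosome 12, 15 to 20 Mb, and 0.674 at chromosome 13, with BXD87 at 0.136 and 0.294. Reads shared between copies of a sequence at the bin and at its distant peaks could give the same values and were not tested.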
